A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

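Trimethylation of histone H3 at lysine 36 (H3K36me3) was measured by chromatin immunoprecipitation on 9 two-colour Agilent tiling arrays, 3 for each of 3 strains of Saccharomyces cerevisiae. The strains were a wild type (WT), a strain lacking the ISW1 remodeller gene (isw1) and a strain lacking the CHD1 remodeller gene (chd1), with 3 biological replicates each, per the labels. On every array the immunoprecipitated DNA (IP) was labelled with Cy5 and the same strain's input DNA with Cy3, per the labels, so no dye swap was present and a dye bias that is the same on all arrays cancels only between strains. The cultures were held with 2 µM alpha factor for 5 h from an optical density of 0.4, per the labels' protocols.

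The scanner files hold fluorescence intensity values on a linear scale. Per the file headers, Agilent Feature Extraction had subtracted the background, corrected spatial and multiplicative trends and applied a linear dye normalization before the processed intensity was deposited. The outlier and above-background marks were also set by that software, per the file headers. A second table holds the authors' log2 values for the same arrays. R 2.13.0 is named in the submitters' processing notes, and the steps behind that table are not given in the sources used here. Set against the log2 IP/input of each array, the authors' deposited log2 values had a correlation of 0.997 to 0.998 across probes and a slope of 0.940 to 1.16. Their medians lay between 0.0055 and 0.0215. Scale, centring and direction were therefore those of a median-centred log2 IP/input, but how the spread of the arrays was adjusted stays unknown.

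From the scanner files, the log2 of processed Cy5 over processed Cy3 was taken for 60647 probes after control spots were removed, outlier-marked spots were set to missing, and each array was centred on its median. No loess or quantile step was used, since most probes can carry signal. All values are relative to input, not to total histone H3, so nucleosome density and methylation per nucleosome were not separated. Between 99.4% and 99.6% of probes were well above background in both channels on each array, and the median input signal per array ran from 811.8 to 4223. Arrays have no read depth, and their number limits the precision.

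Probe positions are those of sacCer1, the build the probe names carry, and no positions from another build are printed. Of 7330 gene names in the files, 5619 matched a locus in the RefSeq gene table of assembly R64, which was used for current symbols and for the length of each gene, and not for positions. The files assign promoter and coding probes to one name. A coding region was therefore placed by its neighbours: its 5' end where probes of a divergent promoter adjoin it, its 3' end where the next gene lies on the same strand, and the other end by its length. In 1259 genes bounded on both sides, the probe span differed from the length by a median of -130 bp, against a median probe spacing of 181 bp. For 1518 unplaced genes only probes certain to lie inside the coding region were kept. In 1 of the genes tested, the name in the files matched a locus of the same name on another chromosome, so its value belongs to a different gene; it was found after the fits, remains in the counts and is not named. This left 39918 coding probes and 4914 genes with at least 2, of which 4910 had values on all arrays. Lengths were multiples of 3 in 96.3% of genes, so they are coding lengths, with introns included where a gene has them. No untranslated regions were used. Divergent promoters (4610 probes) stood for intergenic DNA.

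A gene value is the mean over its coding probes. Polarity is the mean over the 3' segment minus the mean over the 5' segment when the coding region is split into 3 equal parts, for 2337 genes of at least 1000 bp with at least 2 probes in each segment. Genes, polarity and probes were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, all 9 arrays in one fit and no covariates, and Benjamini-Hochberg adjusted p-values were held against 0.05 over all features of a contrast. Adjusted p-values quoted for single genes come from these limma fits. Average profiles (500 bp of 5' flank, 5 equal parts of the coding region, 500 bp of 3' flank), medians of 4 length classes and the contrast between coding and promoter probes were compared by an exact two-sided permutation test, which with 3 against 3 cannot give a p below 0.1. The 16 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. The lists were a-specific genes, alpha-specific genes of the other mating type, core histone genes, cytosolic ribosomal protein genes, G1/S genes, G2/M genes, glucose-repressed and inducible genes, glycolysis and fermentation genes, heat shock and chaperone genes, meiosis and sporulation genes, pheromone response genes, genes reported to hold Set2-pathway cryptic promoters, ribosome biogenesis genes, factors of the Set2-Rpd3S pathway, elongation and remodelling, strain marker genes, and genes within 20 kb of a chromosome end.

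Genes were named by a rule fixed before the data were examined. For each gene contrast it takes the 10 largest rises and 10 largest falls among genes past the threshold whose 3 replicates in one strain all lay on the same side of the 3 in the other, and for polarity the 5 and 5 by the same rule. ISW1, CHD1, SET2, FLO8, STE11 and PCA1 were added, as were the 4 largest changes in each list that passed the threshold, or the 2 largest as values where none did. Not every gene that the rule takes is named. ISW1 and CHD1 in contrasts with their own deletion, and BAR1, were kept out of the tests of alternatives after their values were seen, because ISW1 and CHD1 are deleted in a strain compared there and no BAR1 probe was well above background in the IP. FLO8 had no matched probes and was not analysed here.

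The arrays fell into 2 scans: the first held replicates 1 and 2 of every strain and the second held replicate 3 of every strain. Scan was therefore tried as a block, and values were computed within each scan. The files did not tell slides apart, so slide as a block was not run. The other alternatives were normexp background correction (offset 50), loess within arrays, an equal spread on all arrays, the authors' values, only probes well above background, only the 2 groups compared, the replicate number as a block, each array left out in turn, medians over probes, at least 5 probes per gene, the outer segments of a split into 4 for polarity, and genes of at least 2000 bp for the profile. Centring on coding probes, correction for probe GC content, the first scan alone, and polarity only for genes with both ends placed by probes were added after seeing the data.

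The gene test was tested on simulated data with the real spread and 200 changed genes among 4910. It recovered 41.0% of changes of 0.5 log2 and 94.0% of changes of 1 log2 in the simulated chd1 contrast with WT, and 45.0% and 93.0% in the isw1 contrast. For polarity, with 200 changed among 2337 genes, it recovered 18.0% and 86.0% in the chd1 contrast and 19.0% and 90.0% in the isw1 contrast. In the data far more passed against WT: 1840 genes in isw1 and 2109 in chd1, and 742 and 1936 polarity values. An adjusted threshold is stricter where few features change, and the simulated noise was independent between genes. These shares therefore hold for the simulated setting and do not measure the power of the real tests. With 200 of 59974 probes changed, the probe test recovered 0% and 1.0% in the isw1 contrast and 0% and 0% in the chd1 contrast, although the median sizes found were 0.514 and 1.03 in the first, since few changes among many probes leave an adjusted threshold that they seldom pass. With 10000 probes changed, a number raised after that result was seen, it recovered 10.9% and 71.8% in the chd1 contrast and 10.2% and 72.3% in the isw1 contrast. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.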

Results

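H3K36me3, a mark laid down on transcribed coding regions by the methyltransferase Set2, was compared with input DNA in budding yeast that lacked the chromatin remodeller Isw1 or Chd1 and in their wild type. Each strain had 3 biological replicates, each hybridised on its own array of 60647 probes. The comparisons ask where along genes, and over which genes, the mark depends on each remodeller. Cultures carried alpha factor, the mating pheromone that holds a cells in G1. Values below are log2 IP/input relative to the array median, as the mean ± SD of 3 replicates unless another error is named.

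The deleted genes were examined first. CHD1 (YER164W, chromosome 5, probes from 505504 to 509804 in sacCer1) had lost its input signal in the chd1 arrays, where its 24 coding probes kept 4.16%, 0.842% and 2.05% of the mean WT input signal. Only 10, 11 and 15 of these probes were well above background in those inputs, so the shares are approximate. ISW1 (YBR245C, chromosome 2, probes from 708159 to 711358) was lower in the input of every isw1 array but kept 39.9%, 11.4% and 18.9% of the WT signal in replicates 1, 2 and 3. In the IP channel of the same arrays it kept 2.48%, 1.64% and 2.98%. The labels are borne out in direction for all 6 mutant arrays. At a deleted gene the ratio does not describe the mark, so IP/input changes are not given for ISW1 in contrasts with isw1 or for CHD1 in contrasts with chd1. BAR1, which encodes the protease that degrades alpha factor, was not well above background in both channels on any array, and its changes are left out likewise. It remains in the gene counts and in the tests of the a-specific and pheromone response lists. At BAR1 no probe passed in the IP channel of any array.

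**Figure D1:**
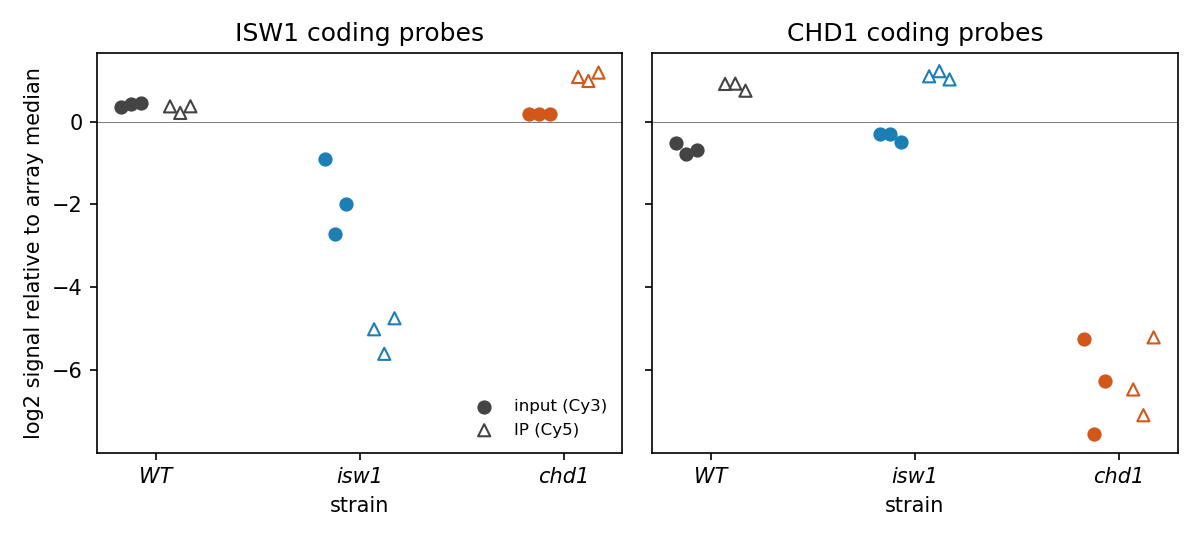
Signal of the ISW1 (left) and CHD1 (right) coding probes on each array, as log2 relative to the array median (vertical axis), by strain (horizontal axis), with filled circles for input and open triangles for IP. CHD1 input lies between -7.56 and -5.25 in the chd1 arrays, while ISW1 input in the isw1 arrays lies between -2.72 and -0.91.

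In WT the mark rose from the promoter into the gene and was highest in its middle and 3' portions. Over genes of at least 1000 bp, the mean was -2.99 ± 0.17 in the 5' flank and -1.35 ± 0.09 in the 3' flank. It was -1.02 ± 0.07 in the first coding part, 0.67 ± 0.01 in the second, 1.15 ± 0.02 in the third, 1.16 ± 0.02 in the fourth and 0.57 ± 0.02 in the fifth. Polarity, the 3' minus the 5' segment, had a median of 1.34 over 2337 genes and was above 0 in 83.1% of them. Long genes carried more of the mark: the median was -1.41 ± 0.04 over 1578 genes under 1000 bp and 1.29 ± 0.02 over 458 genes of at least 3000 bp. Coding probes exceeded divergent promoter probes by 4.61 ± 0.28, and over the arrays of all strains the difference ranged from 3.20 to 4.93.

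In isw1 the shape of the average profile was close to that of WT, but the low signal around genes was higher. At divergent promoters a weaker ChIP contrast in isw1 could not be told apart from a gain, as set out below. The 5' flank was -2.48 ± 0.05 in isw1, 0.51 above WT, and the 3' flank was -1.06 ± 0.06, 0.30 above WT. The first and last coding parts were 0.28 and 0.17 higher, while the third part differed by -0.004, and with loess within arrays the 3' flank differed by -0.02 and the second part by -0.02. At divergent promoters the isw1 median was -3.26 ± 0.04 against -3.86 ± 0.26 in WT, whereas the median over coding probes was 0.74 ± 0.01 against 0.75 ± 0.03. The replicates of isw1 and WT did not overlap in either flank, in the first, second and last coding parts or at divergent promoters, with an exact permutation p of 0.1, the smallest this design allows, and 0.131 after adjustment for the profile over 21 comparisons. Within the first scan the 5' flank difference was 0.39 and within the second 0.74, with scan as a block 0.51. For coding probes relative to divergent promoters the change was -0.43 and -0.97 in the 2 scans.

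The 10 genes with the largest gains that passed in isw1 all lay below the array median in WT. SPR3 (YGR059W, chromosome 7, probes from 607147 to 609098), a sporulation-specific septin gene, rose 5.51-fold, from -3.84 ± 0.27 in WT to -1.37 ± 0.08 in isw1 (log2 change 2.46, SE 0.15, adjusted p = 4.59e-05). TYE7, an activator of glycolytic genes, rose by 2.18 from -5.47 ± 0.33, but its isw1 replicates spread widely (-3.29 ± 0.83), as did those of YCH1, ARG80 and YKR041W, with SDs of 1.06, 0.88 and 0.89. YCH1 (1.71), LCL1 (1.68), ARG80 (1.66), a regulator of arginine metabolism, ERG29 (1.62), YKR041W (1.53), MIM2 (1.52), a mitochondrial outer-membrane import factor, YAL064W-B (1.48) and YOR268C (1.42) followed. The adjusted p of these genes ran from 4.59e-05 for SPR3 to 0.033 for ARG80. With normexp 7 of the 10 calls were lost, those of TYE7, YCH1, LCL1, ARG80, YKR041W, MIM2 and YOR268C (adjusted p from 0.0595 for MIM2 to 0.168 for YKR041W), although the changes stayed between 1.20 for LCL1 and 2.11 for TYE7. With loess all 10 were lost, with SPR3 at 0.44 (adjusted p = 0.196), and the calls at TYE7, YCH1, ARG80 and YKR041W were also lost without some single arrays.

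Among genes that lost the mark in isw1, FMP42 (YMR221C, chromosome 13, probes from 713891 to 715646) fell from 0.11 ± 0.11 in WT to -1.51 ± 0.21, a log2 change of -1.62 (SE 0.13, adjusted p = 6.83e-05). UBP16 (YPL072W, chromosome 16, probes from 418107 to 419968), which encodes a deubiquitinating enzyme, fell from -0.67 ± 0.21 to -2.27 ± 0.09, 3.02-fold. CDC50 changed by -1.58, RMD6 by -1.50, RPE1, an epimerase of the pentose phosphate pathway, by -1.46, and TAD3, a subunit of the tRNA adenosine deaminase, by -1.46. SWT21 (-1.44), the maltose activator gene MAL13 (-1.44) and SAS5 (-1.43), a subunit of a silencing acetyltransferase, completed the 10 with the deleted ISW1. With loess within arrays SAS5 differed by 0.08, and the calls at the other 8, FMP42 and UBP16 among them, were lost. SET2 itself was 1.33 ± 0.14 in isw1 and 1.19 ± 0.03 in WT (adjusted p = 0.374, and -0.01 as a difference with loess). STE11 and PCA1, reported to hold cryptic promoters that the Set2 pathway restrains, differed by -0.25 (adjusted p = 0.108) and 0.28 (adjusted p = 0.043), and the call at PCA1 was lost with normexp (0.16), in the first scan alone (0.181) and whichever single array was left out (0.0654 to 0.146). CHD1 differed by -0.02 in isw1 (adjusted p = 0.974), a value whose sign changes between settings. Its SE of 0.45 is pooled with the chd1 arrays, where the deleted gene had an SD of 1.19, against 0.17 in WT and 0.06 in isw1.

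Of 100 cytosolic ribosomal protein genes, 46 rose in isw1, 1 fell and 53 did not pass (50 and 1 adjusted over the list alone), with RPP2A at 0.89, RPS21A at 0.84, RPS30A at 0.78 and RPL21A at 0.72. The list median was 0.34, against a median of 0.15 over all genes, and camera gave an adjusted p of 1.67e-05 (adjusted p = 0.138 with an estimated correlation). Of 69 ribosome biogenesis genes, 35 rose and 0 fell (38 and 0 adjusted over the list alone), led by SPB1 (1.14), NOP53 (0.92), NOP56 (0.80) and DBP2 (0.74). Camera gave an adjusted p of 5e-05 (adjusted p = 0.38 with an estimated correlation). Within the 2 scans the medians were 0.37 and 0.35 for ribosomal proteins and 0.34 and 0.32 for biogenesis genes. With scan as a block the adjusted p-values were 2.86e-05 and 0.000101.

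Other groups with higher signal in isw1 were smaller. Of 19 G2/M genes 11 rose and 0 fell (12 and 0 adjusted over the list alone), among them HOF1 (0.98), SPO12 (0.71, but -0.05 with loess), BUD4 (0.66) and ALK1 (0.64), with an adjusted p of 0.0032 (adjusted p = 0.38 with an estimated correlation). Of 25 pheromone response genes 8 rose and 0 fell (8 and 0 adjusted over the list alone). The mating adhesin gene FIG2 rose by 1.25 and AGA1, which anchors a-agglutinin in the cell wall, by 1.16, beside KAR5 (0.69) and FUS1 (0.55), with an adjusted p of 0.0486 (adjusted p = 0.956 with an estimated correlation). Of 23 heat shock and chaperone genes 6 rose and 0 fell (6 and 0 adjusted over the list alone), among them MDJ1 (0.64), HSC82 (0.54), SSC1 (0.53) and STI1 (0.42), with an adjusted p of 0.0326 (adjusted p = 0.725 with an estimated correlation). With loess within arrays HSC82 and STI1 differed by -0.20 and -0.19. Scan medians were 0.39 and 0.42 for G2/M genes, 0.31 and 0.27 for pheromone genes, and 0.35 and 0.19 for heat shock genes, and with scan as a block the adjusted p-values were 0.00605, 0.0379 and 0.0291. Without WT replicate 2 the heat shock and pheromone calls were lost (0.141 each), as they were without isw1 replicate 1 (0.0682 and 0.0798) and without isw1 replicate 2 (0.0525 and 0.0899), and the pheromone call was also lost with an equal spread on all arrays (0.113). With loess none of the 6 lists called in isw1 passed.

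Of 119 genes within 20 kb of a chromosome end, 29 fell and 16 rose in isw1 (29 and 16 adjusted over the list alone), and RMD6, MAL13 and ECM34 (-1.17, but 0.09 with loess) fell most, while YAL064W-B rose. The list median was -0.12 (-0.17 and -0.02 in the 2 scans), with an adjusted p of 0.000375, 0.000307 with scan as a block (adjusted p = 0.38 with an estimated correlation). The other lists did not pass in isw1, with adjusted p-values from 0.841 to 0.943. Of 33 meiosis and sporulation genes, 6 rose and 3 fell, among them SSP1 (1.03), SPR1 (-0.85) and SMK1 (-0.81). Of 36 G1/S genes, 10 rose and 8 fell, among them the replication factor RFA1 (-1.12), CDC21 (-0.99), TOS4 (0.98) and POL30 (0.91). Of 21 glucose-repressed and inducible genes, 3 rose, HXT13 (0.61), FLO5 (0.48, but -0.03 with loess) and FLO9 (0.44), and FRE3 fell by 0.43. Of 14 glycolysis and fermentation genes 2 rose, PFK2 (0.48) and GLK1 (0.39, lost with scan as a block at 0.0601 and with normexp at 0.11), and 0 fell. Of 37 factors of the Set2-Rpd3S pathway, elongation and remodelling, 13 rose, including IOC4 (0.92) and the histone chaperone POB3 (0.67), and 5 fell, including RPD3 (-0.68) and the deleted ISW1.

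Several calls at list members in isw1 were weak. With normexp those at NOP53, POL30, SSP1, FUS1, STI1, FLO9, PFK2, GLK1, STE2 and TRP1 were lost (adjusted p from 0.0526 for FUS1 to 0.299 for FLO9), and with medians over probes those at ALK1, SPO12, MDJ1, HSC82, FUS1, STI1, FLO9, PFK2, GLK1, STE2 and TRP1. In the first scan alone those at SSC1, STI1, PFK2 and FLO9 (0.24, adjusted p = 0.223) were lost, and without some single arrays those at NOP53, FUS1, STI1, PFK2, GLK1 and FLO9 (0.28 without WT replicate 3).

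Single genes also differed in polarity in isw1, in both directions. Polarity fell in 442 and rose in 300 of 2337 genes, and the median change was -0.12. The largest rises were at REC114 (3.67), SPR3 (3.11), ZIP2 (2.87), DAL1 (2.86) and RRT12 (2.74). In REC114 (YMR133W), needed for meiotic recombination, the 3' segment went from -5.28 in WT to -3.09 in isw1 and the 5' segment from -0.66 to -2.13. The largest falls were at the hexose transporter gene HXT10 (-2.95), TAF6 (-2.76), PMT5 (-2.58), FUN26 (-2.40) and YNL165W (-2.37). With loess all 10 of these polarity calls were lost. In TAF6, a TFIID subunit gene, the 5' segment rose from -1.92 to -0.003 while the 3' segment went from 1.02 to 0.17. Of 22 meiosis and sporulation genes measured, polarity rose in 10 and fell in 3. SET2, STE11 and CHD1 did not pass for polarity in isw1, with differences of 0.25, 0.36 and -0.01 (adjusted p = 0.449, 0.207 and 0.974), and the sign at CHD1 changed between settings and at STE11 with loess (-0.18).

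In the limma test 1840 of 4910 genes passed in isw1 against WT, 1184 higher and 656 lower, and 10067 of 60647 probes, 7056 higher and 3011 lower. With scan as a block 1805 genes, 712 polarity values and 10366 probes passed. Within the first scan alone 1084, 404 and 5160 passed, with 535 genes higher and 549 lower and 209 polarity values higher and 195 lower, and gene medians were 0.12 and 0.16 in the 2 scans (polarity -0.09 and -0.18, probes 0.17 and 0.26). These counts depend on the background correction and on loess, while an equal spread and the authors' values left 1892 and 1917 genes. Normexp left 830 genes (54.9% of them higher, against 64.3%). Loess within arrays left 1 gene and 1 polarity value and moved the median gene change from 0.15 to -0.004. Of the probes 2201 passed with normexp, 1303 higher and 898 lower, and 19 with loess, 3 higher and 16 lower. The gene count was also 1199 without WT replicate 1 and 1168 with medians over probes (50.0% of them higher), and polarity calls numbered 443 with normexp, 488 without WT replicate 1 and 468 without WT replicate 3. Probe calls numbered 4741, 3820, 5534 and 5215 without WT replicate 1, WT replicate 3, isw1 replicate 1 and isw1 replicate 2. Among genes with both ends placed by probes, 215 polarity values passed, 110 higher and 105 lower (median -0.01).

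**Figure D2:**
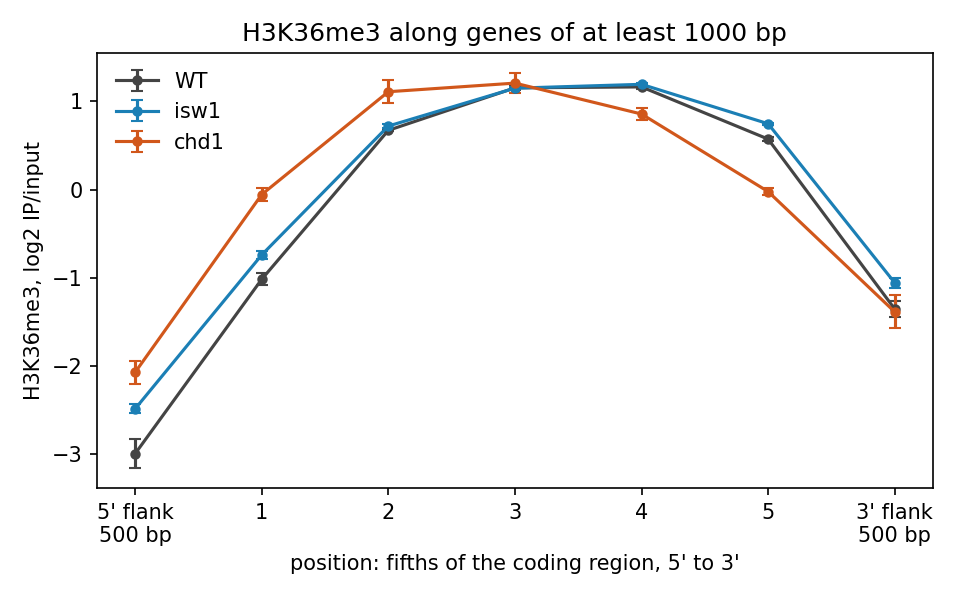
Mean log2 IP/input (vertical axis) over genes of at least 1000 bp in 500 bp of 5' flank, 5 equal coding parts and 500 bp of 3' flank (horizontal axis), with points for the mean and bars for the SD of 3 replicates per strain. The chd1 curve is 0.96 above WT in the first coding part and 0.59 below it in the last (difference -0.59). The isw1 curve is 0.51 above WT in the 5' flank, 0.30 in the 3' flank, 0.28 in the first coding part and 0.17 in the last.

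In chd1 IP/input was higher than in WT in the 5' portion of genes and lower in the 3' portion. In chd1 the first coding part was -0.06 ± 0.08, 0.96 above WT, and the second 1.11 ± 0.13, 0.44 above WT. The fourth part was 0.85 ± 0.07, a change of -0.31, and the fifth -0.02 ± 0.04, a change of -0.59. The 5' flank was 0.92 higher, and the middle part (0.05) and the 3' flank (-0.03, but 0.15 with normexp) differed by less than the spread between replicates. Each of the 5 larger differences had non-overlapping replicates, an exact permutation p of 0.1, the smallest possible, and an adjusted p of 0.131 over 21 comparisons. They were 0.91, 0.41, -0.32, -0.58 and 0.89 within the first scan and 1.05, 0.50, -0.28, -0.63 and 0.98 within the second, in the same order, and unchanged by scan as a block, since the scans are balanced.

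Polarity fell in 1848 and rose in 88 of 2337 genes, with a median change of -1.23 (quartiles -1.85 and -0.64). The median polarity was 0.01 in chd1, and 50.2% of genes were higher in the 3' segment, against 83.1% in WT. At TUF1 (YOR187W, chromosome 15, probes from 683616 to 685295), the mitochondrial elongation factor gene, the 5' segment went from -1.47 in WT to 0.95 in chd1 and the 3' segment from 2.16 to 0.58. Its polarity changed from 3.62 ± 0.11 to -0.38 ± 0.28 (log2 change -4.00, SE 0.19, adjusted p = 2.87e-09). Other large falls were at the galactose sensor gene GAL3 (-3.94), CST6 (-3.94) and the cell wall gene SCW10 (-3.86). Rises were led by SSY5 (2.85), YPR078C (2.80), PGU1 (2.66), ZIP2 (2.61) and HMS2 (2.50). In YPR078C and ZIP2 both segments were below 0 in WT and in chd1. At STE11 polarity changed by -1.29 (adjusted p = 5.14e-05), at ISW1 by -1.96 (adjusted p = 7.27e-07) and at SET2 by -0.47 (adjusted p = 0.0819). With loess the polarity calls at YPR078C (0.41, adjusted p = 0.447), HMS2 (0.37, adjusted p = 0.256) and ISW1 (-0.66, adjusted p = 0.0641) were lost.

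Polarity in chd1 was lower in 34 of 37 ribosome biogenesis genes, 16 of 17 pheromone response genes, all 14 heat shock genes, all 8 glycolysis genes and all 8 ribosomal protein genes measured, and in 19 of 24 factors of the Set2-Rpd3S pathway, elongation and remodelling. Among 22 meiosis and sporulation genes 10 rose and 7 fell, and among 51 subtelomeric genes 12 rose and 30 fell. The median change was -1.03 in 1421 genes of 1000 to under 2000 bp, -1.44 in 578 genes of 2000 to under 3000 bp and -1.57 in 338 genes of at least 3000 bp.

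**Figure D3:**
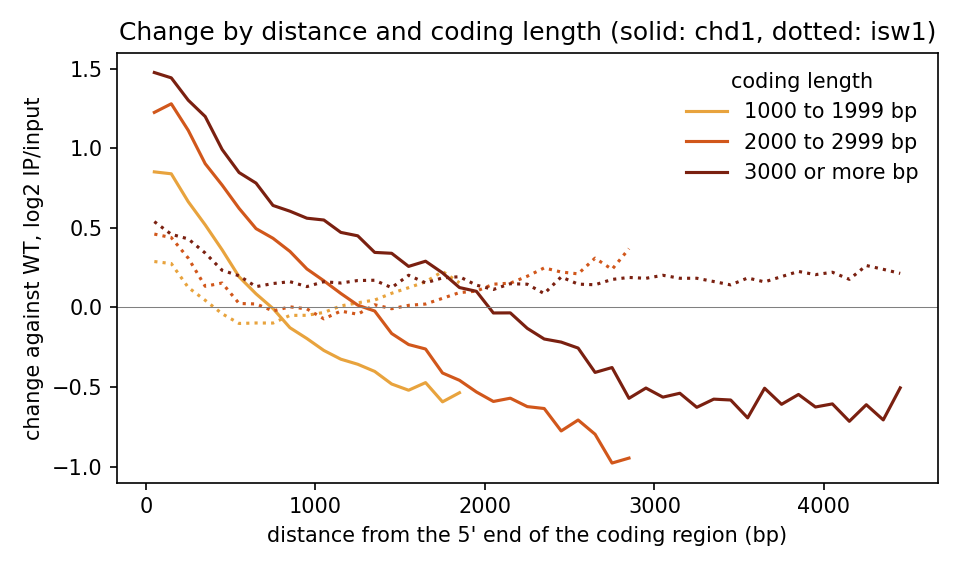
Change against WT in log2 IP/input (vertical axis) by distance in bp from the 5' end of the coding region (horizontal axis), as the mean of 3 replicates in bins of 100 bp with at least 20 probes, in 3 classes of coding length, with solid lines for chd1 and dotted lines for isw1. In genes of at least 3000 bp the chd1 change is 1.48 in the first bin and -0.56 at 3050 bp.

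**Figure D4:**
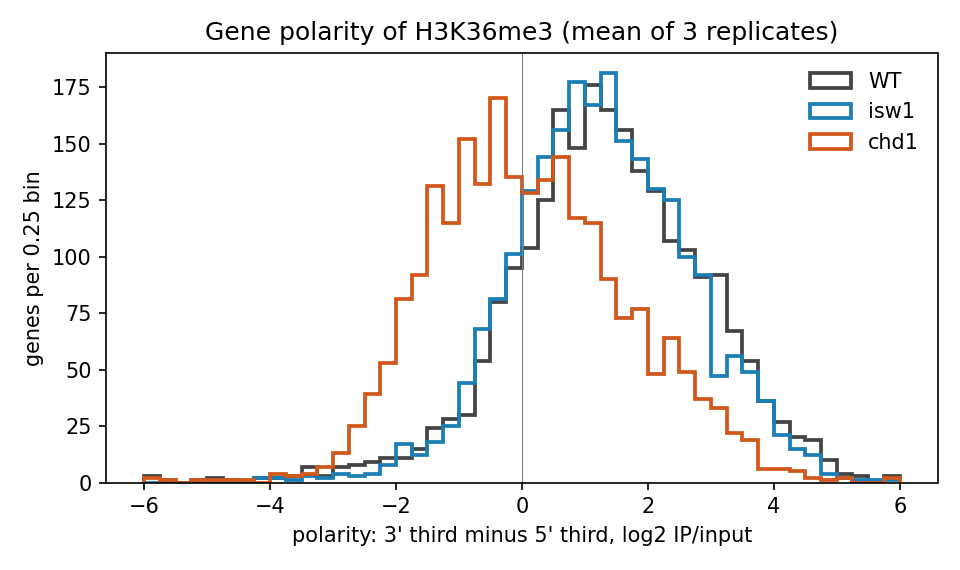
Number of genes per bin of 0.25 (vertical axis) by polarity, the 3' minus the 5' segment in log2 IP/input (horizontal axis), for the mean of 3 replicates of each strain; values beyond 6 are drawn at 6. The chd1 histogram is centred near 0 (median 0.01), and those of WT and isw1 near 1.34 and 1.24.

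Over whole genes, GCN4 (YEL009C, chromosome 5, probes from 137095 to 139701), the activator of amino acid biosynthesis genes, lost most in chd1. It went from 1.53 ± 0.04 in WT to -1.67 ± 0.17, a log2 change of -3.20 (SE 0.11, adjusted p = 1.39e-07), or 9.19-fold. Its input signal was 0.58 higher in chd1, and its IP signal alone changed by -2.62. SAS5 (YOR213C), with 2 coding probes, fell 5.63-fold (-2.49), YNL195C by 2.07, and the paralogous ribosomal protein genes RPS22A (YJL190C, 2 probes) and RPS22B (4 probes) by 2.03 and 1.88. MBF1, a coactivator that works with Gcn4, changed by -1.98, SPG3 by -1.98, the pexophagy receptor gene ATG36 by -1.91, ARG82 by -1.75 and the cell wall gene TOS1 by -1.66.

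The largest gains in chd1 were at genes weakly marked in WT. GPG1 (YGL121C, chromosome 7, probes from 280775 to 281547), which encodes a partner of a G protein, rose 6.79-fold from -4.23 ± 0.10 to -1.47 ± 0.19 (log2 change 2.76, SE 0.11, adjusted p = 5.89e-07). DMO1 rose by 2.26, LCL1 by 2.24, the spindle midzone gene ASE1 (YOR058C) by 2.21, YAL064W-B by 2.21, TYE7 by 2.08, YCH1 by 2.06 and YBL044W by 2.05. Of these genes GPG1, DMO1, LCL1, YAL064W-B and YBL044W rest on 2 coding probes each, and the TYE7 replicates spread widely in chd1 (-3.38 ± 1.43, adjusted p = 0.021). AGA1 (YNR044W, chromosome 14, probes from 703228 to 705820), with 13 probes, rose 4.11-fold from -1.83 ± 0.11 to 0.21 ± 0.35. FIG2 (YCR089W, chromosome 3, probes from 266880 to 272247), with 22 probes, rose 3.73-fold from -1.86 ± 0.16 to 0.04 ± 0.19. SET2 rose by 0.85 (adjusted p = 0.00065), STE11 by 0.44 (adjusted p = 0.0127) and ISW1 by 1.00 (adjusted p = 0.0181), and PCA1 differed by 0.17 (adjusted p = 0.18). With loess the calls at 8 of the 10 largest rises, GPG1, AGA1 and FIG2 among them, and at 5 of the 10 largest falls, SAS5 among them, were lost, and that of TYE7 also with normexp (0.0578), without WT replicate 2 (0.0504), WT replicate 3 (0.0662) or chd1 replicate 2 (0.0692), and without chd1 replicate 1 (1.53, adjusted p = 0.0713). With loess the calls at SET2 (0.51, adjusted p = 0.0702), STE11 (0.15, adjusted p = 0.469) and ISW1 (0.59, adjusted p = 0.28) were lost as well. STE11 was also lost with normexp (0.0609) and in the first scan alone (0.0637), and ISW1 with only probes well above background (0.0516), with medians over probes (0.0605), in the first scan alone (0.0502) and without WT replicate 2 (0.0562). The error at ISW1 is pooled with the isw1 arrays, where the deleted gene had an SD of 0.74, against 0.09 in WT and 0.14 in chd1. That spread raises the p-values at ISW1, so they say little on how stable its change in chd1 is.

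**Figure D5:**
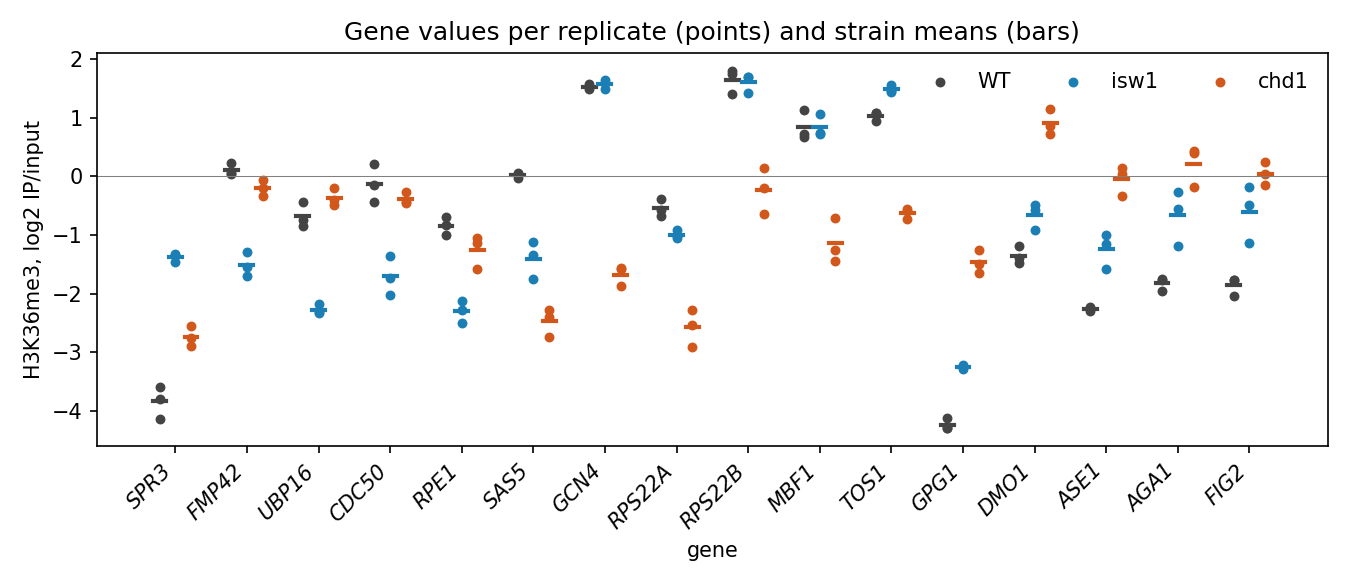
Gene values in log2 IP/input (vertical axis) for 16 named genes (horizontal axis), with a point per replicate and a bar for the mean of each strain. GCN4 lies at -1.67 in chd1 against 1.53 in WT and 1.58 in isw1, while UBP16 and FMP42 are low in isw1 (-2.27 and -1.51).

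Of 69 ribosome biogenesis genes, 47 rose in chd1 and 0 fell (52 and 0 adjusted over the list alone), among them RLP7 (1.54), SPB1 (1.31) and NOP7 (1.28). The list median was 0.50 against 0.15 over all genes, with an adjusted p of 2.35e-08 in camera (adjusted p = 0.57 with an estimated correlation). Within the scans the median was 0.48 and 0.58, and the adjusted p was 4.86e-08 with scan as a block. Ribosomal protein genes split, with 32 higher and 28 lower of 100 (35 and 35 adjusted over the list alone) and an adjusted p of 0.323, and beside RPS22A and RPS22B the largest changes were at RPS4A (1.46) and RPL28 (-1.31).

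Of 25 pheromone response genes, 11 fell and 3 rose in chd1 (11 and 3 adjusted over the list alone). The mating kinase gene FUS3 fell by 1.36 and PRM5 also fell, against the rises of AGA1 and FIG2. The median was -0.21 (-0.13 and -0.51 within the scans), with an adjusted p of 0.00187, 0.0019 with scan as a block and 0.0544 within the first scan (adjusted p = 0.764 with an estimated correlation). Of 36 G1/S genes 18 rose and 4 fell (20 and 4 adjusted over the list alone), among them PCL1 (1.05, but -0.32 with loess), SPT21 (1.05), CDC45 (0.88) and RFA3 (-1.09), with an adjusted p of 0.0337 (adjusted p = 0.764 with an estimated correlation). With scan as a block it was 0.0422, within the first scan 0.0623 and with an equal spread 0.0587, and the scan medians were 0.43 and 0.56. It was also lost with loess (0.094) and without chd1 replicate 1 (0.0675). Of 19 G2/M genes 11 rose and 0 fell (11 and 0 adjusted over the list alone), among them HOF1 (1.08), ALK1 (0.91), BUD4 (0.82) and HST3 (0.80, but -0.05 with loess). Their adjusted p of 0.0391 was lost with scan as a block (0.0613), with normexp (0.0852), with loess (0.319), without WT replicate 1 (0.0529) and without chd1 replicate 3 (0.088), and the scan medians were 0.30 and 0.49 (adjusted p = 0.764 with an estimated correlation).

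The remaining lists did not pass in chd1. Heat shock and chaperone genes had 4 higher and 6 lower of 23 (adjusted p = 0.353), with HSP104 at -0.85, BTN2 at 0.84, FES1 at 0.71 and AHA1 at -0.69. Glycolysis and fermentation genes had 1 higher and 2 lower of 14 (adjusted p = 0.357), with the glucokinase gene GLK1 at -1.36, ADH1 at -0.85 and ENO2 at 0.73. Glucose-repressed and inducible genes had 8 higher and 3 lower of 21 (adjusted p = 0.691), with GAL2 at 0.90 (-0.10 with loess), SUC2 at 0.70, FLO9 at -0.66 and FBP1 at -0.63. Meiosis and sporulation genes had 9 higher and 3 lower of 33 (adjusted p = 0.987), with SPO16 at -1.01 and REC104 at -0.97 (both 0.02 with loess) and NDT80 at 0.92. Subtelomeric genes had 25 higher and 18 lower of 119 (adjusted p = 0.323), with COS6 at -1.38 among those that fell and MRC1 among those that rose. The Set2-Rpd3S, elongation and remodelling list had 17 higher and 2 lower of 37 (adjusted p = 0.197), the 2 being HIR1 (-0.69) and the deleted CHD1, and passed with an equal spread on all arrays (adjusted p = 0.047). Camera sets a list against all other genes, so its direction can be down where the list median is above 0, as for ribosomal protein genes (median 0.05), subtelomeric genes (0.07) and strain marker genes (0.01) in chd1 and for meiosis and sporulation genes (0.04) and strain marker genes (0.18) in isw1. Median and mean differed in sign for a-specific genes (0.31 and -0.01 in isw1, -0.07 and 0.05 in chd1) and, in chd1, for glycolysis genes (0.01 and -0.07), glucose-repressed genes (-0.02 and 0.06) and heat shock genes (-0.01 and 0.004). BAR1 is 1 of the 4 a-specific genes measured, so the values of that list rest partly on a gene without valid signal.

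Among the list members named in chd1, the calls at FLO9 (-0.37, adjusted p = 0.356), FBP1 (-0.28, adjusted p = 0.465), REC104 (-0.38, adjusted p = 0.448) and AHA1 (0.0965) were lost with normexp. AHA1 was also lost with centring on coding probes (0.0643), with only the 2 groups compared (0.0609) and without any one of the WT arrays, and was -0.35 without chd1 replicate 3 and -0.34 in the first scan alone. With medians over probes the calls at AHA1, FBP1, ADH1, BTN2 and HST3 were lost, in the first scan alone that at SPO16, and without some single arrays that at GAL2. With loess the calls at RPL28, RFA3, SPT21, CDC45, HOF1, ALK1, BUD4, SUC2, FLO9, FBP1, GLK1, ADH1, ENO2, BTN2, FES1, NDT80, FUS3, PRM5, SPB1, NOP7, HIR1, COS6, STE6, TRP1 and LEU2 were lost.

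Small lists gave few calls. Of 4 a-specific genes STE6 changed by -0.43 in chd1 and STE2 by 0.54 in isw1 (list adjusted p = 0.402 and 0.841). The STE2 call was lost whichever single array was left out (0.0513 to 0.134), with an equal spread (0.0582), with the authors' values (0.0626) and with centring on coding probes (0.0587), and the STE6 call with an equal spread (-0.20, adjusted p = 0.103), with the authors' values (-0.19, adjusted p = 0.108) and with medians over probes (-0.22, adjusted p = 0.316). Of the 2 alpha-specific genes measured, STE3 had changes of -0.25 in chd1 and 0.22 in isw1, and SAG1 of 0.05 and 0.25, and neither passed (list adjusted p = 0.691 and 0.841). The core histone genes HTA2 and HTB2 differed by 0.04 and 0.36 in chd1 and by 0.36 and 0.44 in isw1, and neither passed (list adjusted p = 0.987 and 0.841). The signs of HTA2, HTB2 and STE3 turn with loess in isw1, those of HTA2 and HTB2 with loess and with an equal spread in chd1, and that of STE3 with normexp in chd1, and HTA2 passed in chd1 with an equal spread on all arrays (-0.32, adjusted p = 0.049). Of 6 strain marker genes, TRP1 rose by 0.94 in chd1 and by 0.95 in isw1, and LEU2 rose by 0.68 in chd1 and fell by 0.83 in isw1, where it differed by 0.11 with loess (list adjusted p = 0.931 and 0.873). The TRP1 call was lost in isw1 whichever single array was left out (0.0503 to 0.104) and in chd1 with medians over probes (0.0768) and without 4 of the 6 arrays, with a change of 0.61 without chd1 replicate 1. Of 3 genes reported to hold Set2-pathway cryptic promoters, 1 passed in each contrast with WT, STE11 in chd1 and PCA1 in isw1 (list adjusted p = 0.691 and 0.841).

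By length, genes of 1000 to under 2000 bp and of 2000 to under 3000 bp had medians 0.13 and 0.17 above WT in chd1, and genes of at least 3000 bp had a median 0.11 above WT. In isw1 the last class was 1.48 ± 0.01, 0.19 above WT, and genes of 2000 to under 3000 bp were 0.10 above WT. Replicates did not overlap for the first 2 of these classes in chd1 or for the last 2 in isw1 (exact permutation p = 0.1, adjusted p = 0.24 over 12 comparisons). Genes under 1000 bp differed by 0.01 in chd1 and 0.04 in isw1. Within the 2 scans the chd1 differences were 0.12 and 0.16 for 1000 to under 2000 bp and 0.15 and 0.21 for 2000 to under 3000 bp. For genes of at least 3000 bp they were 0.07 and 0.18 in chd1 and 0.19 and 0.19 in isw1. With loess within arrays the chd1 differences of the 3 classes from 1000 bp up were -0.002, 0.06 and -0.002, and the isw1 differences of the 2 longest were -0.02 and -0.04.

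In chd1 against WT 2109 of 4910 genes passed, 1416 higher and 693 lower, and 26176 of 60647 probes, 16137 higher and 10039 lower. With scan as a block 2054 genes, 1933 polarity values and 26175 probes passed, and within the first scan 1258, 1798 and 18136. Scan medians were 0.13 and 0.17 for genes, -1.21 and -1.32 for polarity, and 0.16 and 0.20 for probes. The gene count was 1358 with normexp and 1403 with medians over probes (51.1% of them higher, against 67.1%). Loess within arrays left 190 genes (47.9% higher) and 735 polarity values, of which 694 were lower, with a median polarity change of -0.40, and 3183 probes, 1481 higher and 1702 lower. Among genes with both ends placed by probes 554 polarity values passed, 528 of them lower.

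The mutants were compared with each other to separate what was particular to each. Relative to isw1, chd1 had lower polarity in 1838 and higher polarity in 72 of 2337 genes, with a median difference of -1.19. Its first coding part was 0.68 higher and its last was -0.77 relative to isw1, and the 5' and 3' flanks differed by 0.41 and -0.33. These 4 differences had non-overlapping replicates (exact permutation p = 0.1, adjusted p = 0.131). Within the 2 scans the first part differed by 0.70 and 0.65, the last by -0.74 and -0.82, the 5' flank by 0.50 and 0.24 and the 3' flank by -0.24 and -0.51. Among the lowest polarity values relative to isw1 were those of TUF1 (-3.64), the tryptophan permease gene TAT2 (-3.54), CAT2 (-3.41) and CPR7 (-3.40), and the highest were at SEO1 (2.63), CUE2 (2.24), HXT10, PMT5 (1.91) and PGU1 (1.86). With loess the polarity calls at CUE2, HXT10 (0.31, adjusted p = 0.366), PMT5 (0.38, adjusted p = 0.299) and CPR7 (-0.77, adjusted p = 0.0739) were lost.

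By gene, GCN4 was 9.52-fold lower in chd1 than in isw1 (log2 difference -3.25, SE 0.11, adjusted p = 1.19e-07). TOS1 (-2.11), MBF1 (-1.98), RPS22B (-1.83), the replication factor gene RFA3 (-1.83), ATP5 (-1.78), GLK1 (-1.75), the vacuolar protease gene PRB1 (-1.72) and MIX14 (-1.72) were also lower. UBP16 was 3.74-fold higher in chd1 (1.90, SE 0.13, adjusted p = 1.67e-05), followed by GPG1 (1.78), ENA1 (1.75), MDE1 (1.71), YCR101C, the RNA polymerase III factor gene BRF1 (1.69), YRB2 (1.67), YRB30 (1.62) and the acetyltransferase gene SAS3 (1.61). ENA1, a sodium pump gene, rests on 2 coding probes. With loess 6 of these falls, TOS1 and MBF1 among them, and 4 of the largest rises, UBP16 among them, lost their call, and MIX14 did with normexp. SET2 was 0.71 and STE11 0.70 higher in chd1 (adjusted p = 0.00135 and 0.00111), and PCA1 differed by -0.11 (adjusted p = 0.374), but by 0.02 with loess and 0.04 with an equal spread.

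Of 100 ribosomal protein genes 43 were lower and 10 higher in chd1 than in isw1 (45 and 10 adjusted over the list alone), among them RPS26A (-1.50) and RPL32 (-1.48). The adjusted p was 1.66e-05, and 1.48e-05 with scan as a block (adjusted p = 0.15 with an estimated correlation). Of 25 pheromone response genes 16 were lower and 3 higher, with BAR1, which had no valid signal, among the 3 (18 and 3 adjusted over the list alone), including FUS3 (-1.41), GIC2 (-1.37) and SCW10. Their adjusted p was 1.66e-05, and 1.48e-05 with scan as a block (adjusted p = 0.675 with an estimated correlation). Heat shock genes had 10 lower and 3 higher of 23 (11 and 3 adjusted over the list alone), including HSP104 (-1.13), SSC1 (-1.03) and SSA1 (-0.88), with an adjusted p of 0.0114, 0.0107 with scan as a block and 0.0842 with an equal spread (adjusted p = 0.675 with an estimated correlation). G1/S genes had 18 higher and 4 lower of 36 (18 and 5 adjusted over the list alone), including RFA1 (1.24), CTF18 (1.13) and the G1 cyclin gene CLN2 (1.13), with an adjusted p of 0.0092, 0.00952 with scan as a block (adjusted p = 0.675 with an estimated correlation). Ribosome biogenesis genes had 22 higher and 5 lower of 69 (21 and 5 adjusted over the list alone), including MAK16 (0.98), NOP8 (0.95) and NOP14 (0.90), with an adjusted p of 0.0404, 0.0357 with scan as a block, 0.16 within the first scan, 0.101 with normexp and, without isw1 replicate 1, isw1 replicate 3 or chd1 replicate 3, 0.064, 0.0633 and 0.128 (adjusted p = 0.706 with an estimated correlation). The scan medians were -0.28 and -0.33 for ribosomal protein genes, -0.44 and -0.80 for pheromone genes, -0.42 and -0.22 for heat shock genes, 0.39 and 0.39 for G1/S genes, and 0.21 and 0.26 for biogenesis genes. With loess within arrays the calls were lost for ribosomal protein genes (0.103), G1/S genes (0.103) and heat shock genes (0.282).

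The remaining lists did not pass between the mutants, although with loess the glycolysis list and the list of Set2-Rpd3S, elongation and remodelling factors did (adjusted p = 0.0229 each). Subtelomeric genes had 37 higher and 14 lower of 119 in chd1 (adjusted p = 0.193), with YDR541C at 1.42 and COS6 at -1.24. Factors of the Set2-Rpd3S pathway, elongation and remodelling had 11 higher and 9 lower of 37 (adjusted p = 0.515), with RPD3 at 1.02. The 11 include ISW1 and the 9 include CHD1, each deleted in a strain compared here, and both also enter the loess value of that list. Meiosis and sporulation genes had 7 higher and 5 lower of 33 (adjusted p = 0.992), with SPR3 at -1.36 and SPR1 at 1.22. Glycolysis and fermentation genes had 3 higher and 6 lower of 14 (adjusted p = 0.419), with ADH1 at -0.95 and TDH2 at 0.81. Glucose-repressed and inducible genes had 5 higher and 4 lower of 21 (adjusted p = 0.582), with FRE3 at 0.74 and GAL2 at 0.78 (but -0.68 with loess). G2/M genes had 1 higher, KIP2 (0.47), and 2 lower, among them SUR7 (-0.51), of 19 (adjusted p = 0.992). Of the a-specific genes STE6 (-0.67) and STE2 (-0.60) were lower (list adjusted p = 0.419). The 1 called higher was BAR1, which had no valid signal but is part of that list value. Of the strain markers LEU2 (1.52) was higher and HIS3 (-0.73) and URA3 (-0.67) lower (list adjusted p = 0.885). The alpha-specific genes STE3 (-0.47) and SAG1 (-0.20, but 0.11 with loess and 0.31 with medians over probes) did not pass (list adjusted p = 0.419). The histone genes HTA2 (-0.32, but 0.05 with loess and 0.06 with normexp) and HTB2 (-0.08, but 0.32 with normexp) did not pass either (list adjusted p = 0.607). Of the 3 genes reported to hold cryptic promoters STE11 passed (list adjusted p = 0.498).

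Among the list members named between the mutants, the calls at SUR7 (0.0535), TDH2 (0.0717), HIS3 (0.0826) and GAL2 (0.0875) were lost with normexp. GAL2 was also lost with centring on coding probes (0.0553) and with only the 2 groups compared (0.0704), and STE2 with the latter (0.0523) and with the authors' values (0.0512). With medians over probes the calls at SUR7, KIP2, ADH1 and STE2 were lost, in the first scan alone those at TDH2, STE2 and URA3, and without some single arrays those at URA3, GAL2 (0.49 without chd1 replicate 1) and STE2 (-0.39 without chd1 replicate 3). With loess the calls at SET2, STE11, RPS26A, RPL32, RFA1, CLN2, KIP2, SUR7, FRE3, ADH1, TDH2, SSC1, SSA1, SPR3, SPR1, GIC2, MAK16, RPD3, LEU2, URA3, YDR541C, COS6, STE6 and STE2 were lost.

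In all, 2089 of 4910 genes differed between chd1 and isw1, 1162 higher and 927 lower, and 23857 probes, 11809 higher and 12048 lower. With scan as a block 2022 genes, 1905 polarity values and 23616 probes passed, and within the first scan 1471, 1797 and 15916. Scan medians were 0.06 and -0.005 for genes, -1.18 and -1.24 for polarity, and 0.08 and -0.05 for probes. Loess within arrays left 200 genes, 99 higher and 101 lower, 661 polarity values, 612 of them lower in chd1, and 2652 probes. With medians over probes 825 genes were higher and 900 lower, and with normexp 863 were higher and 594 lower. Among genes with both ends placed by probes 589 polarity values passed, 572 of them lower.

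Genes changed in both mutants were counted last. Of 4910 genes, 578 were higher in both mutants than in WT, 193 were lower in both, and 189 were called in opposite directions. Lists drawn independently would share 341 higher, 92.6 lower and 356 opposite calls. Both contrasts use the same WT arrays. With no change in either mutant, simulated groups against shared WT arrays gave 0 shared calls, a mean correlation of 0.502 across genes and a covariance of 0.0121, where the data gave 0.418 and 0.089. The difference in covariance was 0.0769. A simulation with no change yields almost no calls of any kind, so its 0 shared calls are no baseline for those in the data. With 3 WT arrays the controls cannot be split into parts of 2, so part of the excess over independent lists may come from the shared controls. Shared calls were not counted with normexp or loess, which left 830 genes and 1 gene called in isw1. Coding probes exceeded divergent promoter probes by 4.00 in isw1 and 3.54 in chd1, against 4.61 in WT. Whether a weaker ChIP contrast in both mutants gave part of the shared calls was not tested. LCL1, TYE7, YCH1 and YAL064W-B were among the 10 largest rises in both mutants, and SAS5 among the 10 largest falls in both.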

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

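The tests of the input channel and of the remaining ISW1 DNA were chosen only after the result was seen, and the correction for probe GC content was chosen after seeing the data.

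The input signal of GCN4 was 0.58 log2 higher in chd1 than in WT (0.27 ± 0.12 against -0.31 ± 0.09 relative to the array median, SD, n = 3, limma adjusted p = 0.0308), higher in 3 of 3 arrays. It was flagged as the only gene that passed in a mutant's input against WT and also lay above every WT array.

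The first pattern is the gain at the 5' end and loss at the 3' end of genes in chd1. A weaker ChIP contrast would shrink high and low values alike, yet 3' and 5' probes with the same WT level still differed in their change by -1.14 (SD 0.16 over 3 replicates). The input channel alone had a median polarity change of 0.17, against -1.05 for the IP channel alone and -1.23 for IP/input. In the input 207 of 2360 genes passed for polarity, and in the IP 1996. The input was thus not flat, and a change of that sign enlarges the fall in IP/input. Its size argues against the input as the main source. Correction for probe GC content left -1.23, which argues against GC content as the source. A shift of fixed length from the start of the gene was predicted to give a like crossing point in short and long genes. The distance at which the chd1 change crossed 0 was 2.73 times longer in genes of at least 3000 bp (SD 0.21 over replicates). The comparison was with the shortest class of at least 1000 bp, and the point itself depends on how arrays are centred. But a shifted profile can also cross 0 near the WT peak, which lay near 850 bp in the shortest class and 2050 bp in the longest. The ratio therefore cannot decide on a shift of fixed length. With loess within arrays, which removes a trend of the ratio with signal intensity, the median polarity change was -0.40. Polarity calls then numbered 735, against 1936. How much of the pattern comes from such a trend was not tested and stays open. A redistribution of the mark, or of nucleosomes carrying it, along the gene in cells without Chd1 stays open as well. It may be biological and is a hypothesis from these data, since no histone H3 array was analysed here.

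The second pattern is the rise at divergent promoters, 0.60 in isw1 and 1.05 in chd1. In chd1 promoter probes rose by 0.45 more than coding probes of the same WT level (SD 0.07 over replicates), above the bound set in advance. But the coding probes came from whole genes, including 3' portions that fell in chd1. The first pattern alone can therefore give such an excess, and promoters were not set against 5' coding probes only. The excess thus cannot decide on a weaker ChIP contrast at promoters in chd1. In isw1 the excess was 0.10 (SD 0.07), between the bounds set in advance, so a weaker ChIP contrast and a gain at promoters cannot be told apart there. A biological effect of the deletions stays open in both.

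The third pattern is the ISW1 DNA in the isw1 inputs. Cells with ISW1 in the cultures would leave the same share in both channels, but the IP share was 0.144 of the input share (median of 3 arrays, SD 0.05). Cross-hybridisation would leave a like share on every array, and the highest input share was 3.50 times the lowest, but this rests mainly on replicate 1 (39.9%, against 11.4% and 18.9%) and was set after those shares were seen, so cross-hybridisation stays open. ISW1-bearing DNA that entered the inputs after the IP was taken is another possible explanation that was not tested, and a biological one was not tested either. Without isw1 replicate 1, where the share was highest, the counts against WT stayed within 1.5 times for genes and polarity and fell to 5534 for probes.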

How the results depend on the processing

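Centring on coding probes, GC correction, the first scan alone and the restriction to both ends placed were chosen after seeing the data. The fall in polarity in chd1 kept its direction under every alternative, and its count against WT stayed between 1613 and 1943 except with loess and with both ends placed by probes. Using only probes well above background, centring on coding probes, correction for probe GC content, scan as a block, only the 2 groups compared, at least 5 probes per gene and the outer segments of a split into 4 left every main result for which they were run in place, apart from the G2/M list in chd1, whose call was lost with scan as a block. Among 237 changes at named genes, 200 kept direction and side of the threshold with normexp, 57 with loess (156 lost the call), 228 with an equal spread, 225 with the authors' values, 236 with scan as a block and 205 with medians over probes. Slide as a block was not run, because the files did not tell slides apart. Between 99.4% and 99.6% of probes were well above background in both channels, and BAR1 in all strains and HXT6 in both mutants had no probe that was. With both ends placed fewer genes were tested. For all other values below the cause was not tested.

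With normexp the gene counts were 830 in isw1 (against 1840) and 1358 in chd1 (against 2109), polarity calls in isw1 443 (against 742) and probes in isw1 2201 (against 10067). STE3 in chd1 was 0.24, HTA2 and HTB2 in chd1 against isw1 0.065 and 0.32, CHD1 polarity in isw1 0.016, the fourth coding part in isw1 -0.013, the 3' flank in chd1 0.15, and genes under 1000 bp in chd1 against isw1 0.052.

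With loess within arrays, for isw1 against WT, chd1 against WT and chd1 against isw1, gene counts were 1, 190 and 200 (against 1840, 2109 and 2089), polarity calls 1, 735 and 661 (against 742, 1936 and 1910) and probes 19, 3183 and 2652 (against 10067, 26176 and 23857). Lists called numbered 0 in isw1 and 2 in chd1 (against 6 and 4). In isw1 SAS5 was 0.076, SET2 -0.012, STE3 -0.081, HTB2 -0.22, HTA2 -0.10, SPO12 -0.050, FLO5 -0.034, HSC82 -0.20, STI1 -0.19, LEU2 0.11, ECM34 0.086, STE11 polarity -0.18 and CHD1 polarity 0.21. In chd1 HTB2 was -0.48, HTA2 -0.050, PCL1 -0.32, HST3 -0.052, GAL2 -0.10, SPO16 0.020 and REC104 0.019. In chd1 against isw1 PCA1 was 0.019, SAG1 0.11, HTA2 0.051 and GAL2 -0.68. In the isw1 profile the second part was -0.022, the fourth -0.068 and the 3' flank -0.024. By length, chd1 was -0.043 under 1000 bp, -0.0022 from 1000 to under 2000 bp and -0.0022 from 3000 bp, isw1 -0.022 from 2000 to under 3000 bp and -0.037 from 3000 bp, and chd1 against isw1 0.035 from 3000 bp.

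With an equal spread HTB2 and HTA2 in chd1 were -0.052 and -0.32, PCA1 in chd1 against isw1 0.040, genes under 1000 bp in chd1 -0.14 and genes from 3000 bp in chd1 against isw1 0.068. With the authors' values CHD1 in isw1 was 0.00031, HTA2 in chd1 -0.28, PCA1 in chd1 against isw1 0.042, the third part in isw1 0.0043, genes under 1000 bp in chd1 -0.12 and genes from 3000 bp in chd1 against isw1 0.060. With medians over probes the gene counts were 1168 in isw1 and 1403 in chd1, CHD1 in isw1 was 0.10 and its polarity 0.15, HTA2 in chd1 -0.38 and SAG1 in chd1 against isw1 0.31. In the first scan alone 1084 genes passed in isw1 and 1258 in chd1, 404 polarity values and 5160 probes in isw1, and STE3 in isw1 was -0.099, HTA2 in chd1 -0.053, HTB2 in chd1 against isw1 0.38 and CHD1 polarity in isw1 0.12. With both ends placed, polarity calls were 215, 554 and 589 in the 3 contrasts. In genes of at least 2000 bp the third part was 0.093 in isw1 and -0.011 in chd1 against isw1. With an estimated correlation 0 lists passed in isw1, 0 in chd1 and 0 in chd1 against isw1.

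Without single arrays the lowest and highest values were as follows. Gene counts ran from 1199 to 1593 in isw1, 1547 to 2225 in chd1 and 1620 to 2142 in chd1 against isw1, polarity calls from 468 to 643, 1858 to 1940 and 1837 to 1904, and probes from 3820 to 8331, 20438 to 25270 and 19489 to 23515. The third part in isw1 ran from -0.014 to 0.0056, the 3' flank in chd1 from -0.14 to 0.041, genes under 1000 bp from -0.037 to 0.057 in chd1 and from -0.073 to 0.021 in chd1 against isw1. CHD1 in isw1 ran from -0.086 to 0.077 and its polarity from -0.12 to 0.075, HTA2 in chd1 from -0.11 to 0.15, SAG1 in chd1 from -0.030 to 0.11 and HTB2 in chd1 against isw1 from -0.40 to 0.33. Lists called numbered 4 to 6 in isw1, 3 to 4 in chd1 and 4 to 5 in chd1 against isw1.

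The replicate numbers are not a pairing. Arrays with the same number had deviations from their group means that correlated by -0.399 to 0.388 (other pairs by -0.382 to 0.303), 4 of 9 such pairs exceeded 0.1, and 2 of 9 arrays correlated best with their own number. With the replicate number as a block 1700, 1964 and 1971 genes, 689, 1929 and 1900 polarity values and 9447, 25527 and 22898 probes passed in the 3 contrasts, and 6, 3 and 5 lists. Counts moved by less than 1.5 times, and among the lists and the named genes the block changed no other call than those of the G2/M list in chd1 (adjusted p = 0.0513), PCA1 in isw1 (0.0573) and GLK1 in isw1 (0.0802).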

Other observations

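The comparison of the input channel between strains was chosen after the data were seen.

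The point along the gene at which chd1 changed from more to less of the mark than WT followed gene length. It lay at 742 bp in 1567 genes of 1000 to under 2000 bp, 1287 bp in 580 genes of 2000 to under 3000 bp and 2024 bp in 339 genes of at least 3000 bp, or 52.4%, 54.6% and 55.2% of the median length of the class. The single chd1 replicates gave 43.5%, 56.6% and 54.6% in the shortest class and 49.6%, 55.7% and 60.2% in the longest. The point depends on where arrays are centred. The ratio of the longest to the shortest class was 2.73. The WT level was highest near 850 bp, 1150 bp and 2050 bp in the 3 classes, close to these points. A shift of one fixed length could also cross 0 there, so the ratio does not tell it from one that scales with the gene. In long genes the isw1 change fell from 0.54 near the start to 0.13 at 650 bp and stayed above 0 along the gene.

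BAR1 had no signal well above background in both channels in any strain, including WT, where its mean input signal over 4 probes was -7.42, -7.90 and -8.13 log2 relative to the array median in replicates 1, 2 and 3. It was -4.84, -6.96 and -7.10 in isw1 and -6.85, -9.27 and -8.82 in chd1, with at most 1 of the 4 probes well above background on any array. The deleted CHD1 lay at -5.25, -7.56 and -6.27 in the chd1 inputs, and 99.8% of probes were well above background in each WT input. The WT input thus held about as little BAR1 signal as that of a deleted gene, and the genotype at BAR1 was not tested. Mitochondrial probes had a median IP/input of -9.22 ± 0.49 in WT, -8.77 ± 0.32 in isw1 (SD, n = 3), and were 1.22 higher than WT in chd1, where the SD was 1.31. In the input channel, PUS2 was 0.72 higher in chd1 than in isw1 (limma adjusted p = 0.00841), MIM2 0.65 higher (adjusted p = 0.0248) and RRN5 0.49 higher (adjusted p = 0.0458). These genes were chosen after their values were seen, as all those called in the input channel between the mutants beside ISW1, CHD1 and GCN4.

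For other splits of the 6 arrays of a contrast, the 10 possible splits are too few for a share under 0.05. The real split of isw1 against WT gave 1840 genes and the highest other split 7, and for polarity 742 against 0 and for probes 10067 against 0. For chd1 against WT the real split gave 2109 genes, 1936 polarity values and 26176 probes, and for chd1 against isw1 2089, 1910 and 23857, with 0 in the highest other split in each case. In each of the 9 counts only 1 of the 10 splits, the real one, reached the real value. Every other split puts arrays of both strains on each side, so differences between strains enter the spread and few calls can follow. The low counts of the other splits are therefore no measure of the calls that would arise without a difference.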
